A study of Drosophila melanogaster with 2 samples.

How the data were processed

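The study measured RNA, accessible chromatin and chromatin contacts in nuclei of Drosophila melanogaster embryos collected over 0 to 24 h. Per the labels' protocols, nuclei were crosslinked, cut with restriction enzymes, proximity-ligated and barcoded on the 10x Genomics platform. The deposited matrix holds UMI counts per gene and nucleus, whole numbers that the authors had not normalized. That they count UMIs rather than reads follows from the platform named in the labels. The aligner, the counting program and the filters on barcodes are not given in the sources used here. The submitters' processing notes name the genome build dm3. Nuclei carry names made by the authors, by a rule that is not given in the sources used here. The labels give 1 RNA library and 1 library of accessibility and interactome, no second condition and no replicate. The second library was not analysed here.

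The library had 2233526 UMIs in 318 nuclei. All nuclei had at least 200 genes and were kept. Counts were clustered in scanpy 1.11.5 (python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Each nucleus was scaled to 10000 UMIs and log-transformed. Genes found in at least 3 nuclei entered the choice of 2000 variable genes, and 20 principal components and 10 neighbours were used for Leiden clustering (igraph 0.11.9) at resolution 1.0 with random seed 0. Genes were not scaled to unit variance. The 914 comparison-list genes that were not cell type markers, ribosomal RNA among them, were left out of the variable genes. No gene of the mitochondrial genome was in the table.

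Cell types came from 25 marker lists. A cluster took the name of the list with the most members that were over 2-fold higher than in all other nuclei with at least 5 UMIs, if at least 3 markers passed and no other list had as many. A cluster with a median under 989.7 UMIs, the library's median divided by 3, and no such marker among its 10 leading genes stayed unnamed. Clusters 2 and 6 stayed unnamed too, the former because of its leading genes and the latter because of the markers sisA and fkh, which are not among its 10 leading genes. The midgut-like cluster, at a median of 1011 UMIs, lay just above that limit, and neither it nor the amnioserosa-like cluster had such a marker among its 10 leading genes. The marker and comparison lists, the clustering settings, the rule for named genes and most alternatives were fixed before the data were examined. The thresholds of the naming step, the names withheld from clusters 2 and 6 and the class and list pairs described were set after the values were seen. Doublets were scored with Scrublet, which called 8 of the 318 nuclei. They were kept, and leaving out the highest scores is among the alternatives. Of the list entries, 37 were not found under their exact symbol, of which 27 were found through an older symbol in the reference table and 10 were not. No coordinates or chromosomes were taken from that reference, which is of another release than dm3. The share of X-linked genes was therefore not run.

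Comparisons used sums of UMIs in a class against those in all other nuclei, as CPM (counts in 1000000 UMIs). Rankings of single genes, median log2 folds of lists and counts of genes, members or markers past 2-fold or 5-fold used CPM + 10 in both groups. Printed folds of single genes and of sums of lists are ratios of CPM without that addition. Intervals are exact at 95%: Clopper-Pearson for shares, Poisson for CPM, and the conditional binomial interval for ratios of Poisson counts. They leave out all variation between nuclei and embryos. List medians were taken over members with at least 20 UMIs that were not markers, in lists of at least 4 such members, and set against 10000 random lists matched in 20 bins of expression. No p-values were computed, since nuclei are not replicates. Thinning drew 1000 UMIs per nucleus without replacement from the 270 nuclei that had as many, and left out 48. Hox pairs were compared with the number that independence gives within classes and 3 depth groups of equal size.

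Named genes were fixed by rule: the 20 genes with the most UMIs, the 10 genes leading each cluster by fold with at least 20 UMIs and UMIs in at least 20% of its nuclei (identity of the cluster, not a result), up to 4 members of each list named, those with the highest and lowest fold, every Hox gene, roX1, roX2, msl-2 and Sxl, and markers of a class with at least 10 UMIs. The midgut markers GATAe and betaTry, the amnioserosa markers ush, C15 and tup and the ring gland markers phm and spok had fewer UMIs than that in their class or cluster. They and the counts of the germ cell genes and of the deepest nucleus of cluster 2 were added after the values were seen.

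The steps were tested on simulated counts drawn from the real gene means and depths, with cluster 1 against all other nuclei and 7983 genes with at least 20 UMIs. Of 200 changed genes, the 50 at 2-fold came back with a median of 1.83-fold, the 50 at 4-fold with 3.25-fold, the 50 at 0.5-fold with 0.574-fold and the 50 at 0.25-fold with 0.387-fold, on the scale with CPM + 10 that draws low genes towards 1. The intervals held the simulated ratio for 98%, 98%, 94% and 96% of them. A list of 20 genes at 2-fold lay at the 100 percentile, and 4.5% of 200 unchanged lists lay beyond the percentiles. These counts were Poisson with 1 rate per gene in each group, as the intervals assume, and genes varied independently. The simulation therefore checks the computation and cannot show how the intervals or percentiles hold with real variation between nuclei. Counts simulated from the profiles of the 12 clusters gave 13 clusters, with an adjusted Rand index of 0.948. Those profiles were the clusters' own, and on the real counts another random seed gave an index of 0.739.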

Results

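RNA was counted in single nuclei of Drosophila melanogaster embryos collected over a window of 0 to 24 h, which spans embryogenesis from the first nuclear divisions to about the time of hatching. The assay, scAIR, cuts and ligates the chromatin of crosslinked nuclei before droplet barcoding, so that RNA, open chromatin and chromatin contacts can be read from the same nuclei. The analysis covers 1 RNA library. The matching accessibility and interactome library was not analysed here. The library held 318 nuclei and 2233526 unique molecular identifiers (UMIs) from 11735 of the 17039 genes in the table. A nucleus held a median of 2969 UMIs (quartiles 1393 and 7576.75, range 279 to 123309) and a median of 1372.5 genes. The deepest 32 nuclei carried 48.5% of all UMIs, so sums over nuclei weigh a few nuclei heavily. With 1 library there is no replicate check, and the intervals given here cover counting error only. How many embryos were pooled is not given in the sources used here.

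Genes of protein synthesis dominated the RNA of these nuclei, beside tissue products of late embryos. Cytosolic ribosomal proteins made up 25.05% of UMIs (exact binomial 95% interval 24.998% to 25.111%), and 15 of the 20 genes with the most UMIs encode them. RpL41 led with 11258 CPM (counts in 1000000 UMIs; exact Poisson interval 11120 to 11399), followed by the translation elongation factor eEF1alpha1 at 6850 CPM and RpS29 at 5198 CPM. The other genes among the first 20 were the poly(A)-binding protein pAbp (4847 CPM), the lipoprotein precursor apolpp of fat body (4851 CPM), the secreted protein Nplp2 (4564 CPM) and CG13159 (3956 CPM). Nuclear genes of oxidative phosphorylation took 1.79% of UMIs, sarcomere genes 1.73% and cuticle proteins 0.579%. The cuticle list was filled by symbol prefix and also took in Cpr, a cytochrome P450 reductase, with 350 of its 12938 UMIs. Genes of adult or later tissues were close to absent: eggshell and yolk genes had 12 UMIs, testis genes 18, larval storage and glue genes 9, and Y-linked genes 4. Ribosomal RNA took 0.248%.

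Nuclei with the expression of several differentiated embryonic tissues were found. The 318 nuclei fell into 12 clusters, 7 of which were named by markers, as 6 classes holding 186 nuclei (58.5%). Under 11 other settings of the clustering these 6 names covered 31.4% to 55.0% of nuclei. Neuron-like nuclei (57 nuclei, 17.9%, exact binomial interval 13.9% to 22.6%) and epidermis-like nuclei were about equally many, and epidermis-like nuclei were more numerous under 3 of those settings. They were higher in 11 neuronal markers, among them nSyb and Syt1, both proteins of synaptic vesicles (488 against 62.2 CPM and 683 against 110 CPM in all other nuclei). They were also higher in 6 markers of sensory organs, among them cpo (4916 against 796 CPM), so sensory neurons were not separated from other neurons. Epidermis-like nuclei (54 nuclei, 17.0%, 13.0% to 21.6%) were made of a cluster led by cuticle genes (Ccp84Ae, Lcp65Ac) and a cluster led by Osiris genes (Osi9, Osi18, Osi20, Osi7) and by sha and m, which shape the apical extensions of epidermal cells. These clusters were also higher in 5 and 7 tracheal markers, such as the chitin deacetylases verm and serp in the second, so tracheal nuclei were not separated from epidermis. Somatic muscle-like nuclei (41 nuclei, 12.9%, 9.41% to 17.1%) were higher in 18 muscle markers, with muscle myosin Mhc at 5910 against 435 CPM and the titin-like bt at 5370 against 279 CPM.

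Smaller classes were named by markers of the midgut, the salivary gland and the amnioserosa. The salivary gland-like class held 7 nuclei (2.20%, 0.889% to 4.48%) with 7 markers, among them the transcription factors CrebA (3237 against 342 CPM) and sage (405 against 9.16 CPM) and the sulfotransferase pip (4693 against 40.7 CPM). Midgut-like nuclei (18 nuclei, 5.66%, 3.39% to 8.80%) were higher in the gut transcription factor GATAe, mex1, alphaTry and betaTry, each on 7 to 14 UMIs that came from 4, 5, 1 and 2 of the nuclei. Their leading genes included mesh, Ssk and Tsp2A, the components of smooth septate junctions, with mesh found in 6 of the 18 nuclei (33.3%) and in 33.3% of all others. The deepest nucleus held 43.4% of the UMIs of this class, so a few nuclei carry its name. The amnioserosa-like class (9 nuclei, 2.83%, 1.30% to 5.30%) rested on 4 markers, peb, ush, C15 and tup, on 15, 6, 7 and 9 UMIs. Without a minimum of UMIs in the class, 5 of 9 amnioserosa markers were over 2-fold higher (median log2 fold 1.45), and so were 5 of 12 midgut markers (0.79), both on the scale with CPM + 10. The midgut and amnioserosa classes were the least stable. The midgut name was given under 5 of the 11 other settings, the amnioserosa name under 2 and the epidermis name under 10, whereas the neuron, muscle and salivary gland names were given under all 11. The muscle share lay between 6.92% and 11.3% under those settings, below its value here in each, and the neuron share between 7.41% and 20.8%.

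**Figure D1:**
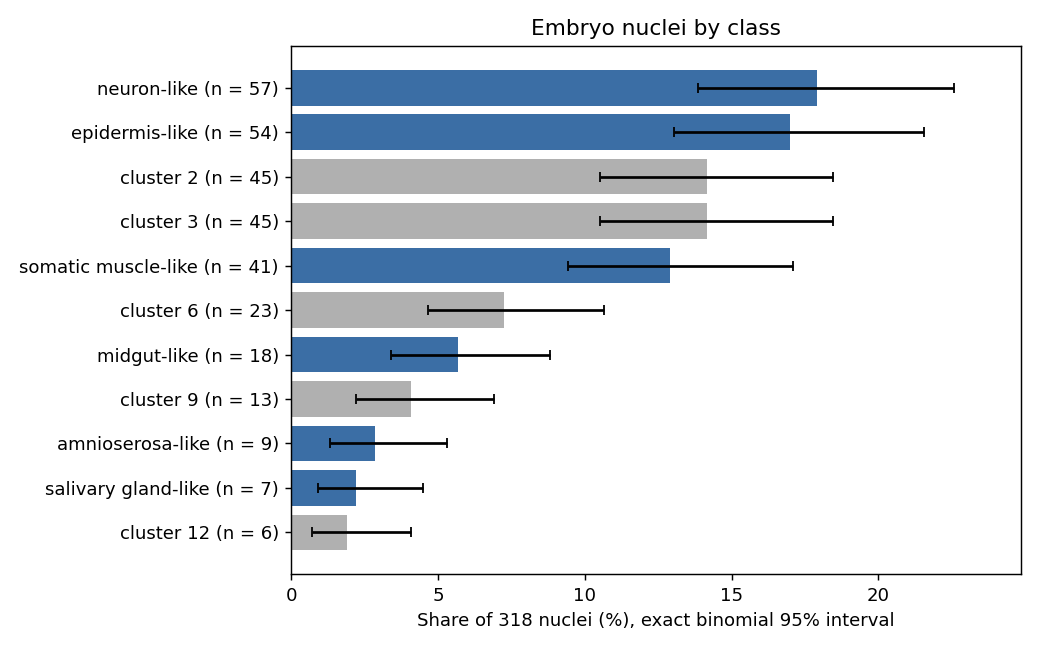
Bars show the share of the 318 nuclei in each class or unnamed cluster (horizontal axis, percent), with exact binomial 95% intervals as error bars. Blue bars are classes named by markers, from 17.9% for neuron-like to 2.20% for salivary gland-like nuclei, and grey bars are clusters left without a name.

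The remaining 132 nuclei (41.5%) lay in 5 clusters that were given no name. Cluster 2 (45 nuclei, 14.2%) was led by transcripts of the oocyte, among them the thioredoxin dhd, the vitellogenin receptor yl, osk, which founds the germ plasm, and wisp, a poly(A) polymerase of the egg. These were little more widespread there than elsewhere, or less so. dhd was found in 60% of its nuclei and 53.5% of the others, yl in 20% and 16.1%, osk in 28.9% and 20.9%, and wisp in 22.2% and 33.7%. The cluster had more germ cell markers (6) than of any other type. The germ cell genes vas, nos, pgc, zpg and bam together were 5.71-fold higher there than in all other nuclei (4.58 to 7.09), but a single nucleus held 65 of the cluster's 78 UMIs of pgc and 13 of its 18 of vas, and without it the fold was 1.85 (1.21 to 2.74). At 1000 UMIs per nucleus 9 of its 35 nuclei held a UMI of these genes, and 25 of the 235 others. The cluster was left without a name because oocyte transcripts led it, and whether it holds germ cells was not settled. Cluster 3 (45 nuclei, 14.2%) was the deepest, with a median of 10152 UMIs and 30.4% of all UMIs, and 4 genes led it by 5-fold or more on the scale with CPM + 10. Cluster 6 (23 nuclei, 7.23%) was higher in the fat body markers apolpp (26830 against 2814 CPM), srp, Lsd-1 and Tps1. It was also higher in sisA, an X-counting factor also active in yolk nuclei (206 against 19.1 CPM), and in fkh, a forkhead factor of gut and salivary gland (1562 against 140 CPM, with UMIs in 22 of 23 nuclei). These last markers go against a fat body name. Leaving clusters 2 and 6 without a name was decided after their genes were seen.

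To see which functions set the classes apart, 34 gene lists were compared between each class and all other nuclei, by members left out of the clustering. Related genes, such as the muscle marker Mhc and the cuticle gene Lcp65Ac, were not left out of it. Of the 374 pairs of a list and a class, 109 had a median fold beyond the 2.5 and 97.5 percentiles of 10000 random lists matched on expression. Of these 42 lay above and 67 below. If genes and pairs were independent, 18.7 pairs would lie beyond them. Genes of a list can vary together and each class is in the reference of the others, so that number is not a measure of chance here. With every nucleus thinned to 1000 UMIs 80 pairs were beyond the percentiles, and 62 of the 109 were among them. The class and list pairs described here were chosen after the values were seen.

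Neuron-like nuclei were higher in genes of excitability, synaptic transmission and cell recognition. Ion channel genes were 5.77-fold higher (exact interval 5.44 to 6.12), with 19 of 24 members at least 2-fold higher, led by the voltage-gated sodium channel para (10.8-fold, 2180 against 202 CPM) and its auxiliary subunit tipE (13.0-fold). With the deepest nucleus of each class left out the fold was 4.59. The lowest members, Irk3 and sand, had 1 UMI each in neuron-like nuclei against 48 and 51 elsewhere, and their intervals of the ratio include 1. Genes of transmitter synthesis, transport and reception were 5.32-fold higher (4.98 to 5.69, 27 of 33 members at least 2-fold higher), among them the vesicular acetylcholine transporter VAChT (9.30-fold) and the metabotropic GABA receptor GABA-B-R1 (10.7-fold). The lowest members, the glutamate receptor subunits GluRIIC and GluRIIB, had 1 and 0 UMIs in neuron-like nuclei against 39 and 20 elsewhere, and their intervals of the ratio include 1 (0.00679 to 1.63 and 0 to 2.17). The cell-surface families dpr, DIP, beat and side, which take part in the choice of synaptic partners, were 3.70-fold higher (3.39 to 4.04, 28 of 37 at least 2-fold higher), led by beat-Ic (12.4-fold) and DIP-kappa (9.69-fold). The transmitter list reached 8.27-fold when each nucleus was weighed the same.

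Lists of broader use moved less in the same nuclei. Neuronal RNA-binding proteins were 2.24-fold higher (2.16 to 2.33), with 5 of 13 at least 2-fold higher, among them shep (4.60-fold) and bru3 (3.39-fold), while Rbp9 had 0 UMIs there and 59 elsewhere. Axon guidance and adhesion genes were 1.80-fold higher (1.72 to 1.88), 13 of 30 by at least 2-fold, from the Slit receptor robo3 (6.78-fold) and the adhesion molecule Dscam2 (6.06-fold) to the immunoglobulin protein Ama at 0.533-fold (0.393 to 0.709). Cytosolic ribosomal proteins were at 0.700 times the level of the other nuclei (0.693 to 0.708), and none of the 85 measured members was higher. Glycolysis genes were 1.68-fold higher (1.56 to 1.81), but 1.18-fold once the deepest nucleus of each class was left out.

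Epidermis-like nuclei were higher in the genes that build and modify the cuticle. Cuticle proteins were 6.02-fold higher (5.81 to 6.24), and 39 of 50 measured members, the reductase Cpr included, were at least 2-fold higher. The highest were Ccp84Ae (24.5-fold, 16.0 to 38.8) and TwdlL of the Tweedle family (11.2-fold, 9.55 to 13.3), while Cpr78E had 0 UMIs in these nuclei and 33 elsewhere. Chitin-modifying genes were 3.01-fold higher (2.69 to 3.36), all 11 above the other nuclei, with expansion (exp) at 5.32-fold and the chitinase Cht7 at 4.22-fold. The list of zona pellucida proteins, which anchor the apical membrane to the cuticle, was 2.12-fold higher (1.76 to 2.53), with pot at 2.81-fold and dyl at 2.27-fold. Among its 5 measured members was papi, which is not of this family, at 1.08-fold on 11 of the 169 UMIs. Transmitter genes were at 0.529 times the level elsewhere (0.471 to 0.592), where the neuron-like nuclei are included. They stood at 1008 CPM, and at 1296 CPM in all nuclei outside the neuron-like class.

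Somatic muscle-like nuclei were higher in contractile and energy genes and, against all other nuclei together, lower in those of mitosis. All 11 sarcomere genes outside the marker set were at least 2-fold higher, and their sum was 6.79-fold higher (6.44 to 7.17), with the thick-filament protein Mf at 9.87-fold and the troponin C gene TpnC47D at 8.97-fold. Glycolysis genes were 1.82-fold higher (1.73 to 1.93), led by lactate dehydrogenase Ldh (3.01-fold) and the aldolase Ald1 (2.46-fold). Oxidative phosphorylation genes were 1.24-fold higher (1.21 to 1.26), a small shift shared by 58 of 65 members. Genes of G2 and mitosis were at 0.684 times the level elsewhere (0.629 to 0.743), with the kinase polo at 0.536 (0.352 to 0.790). They stood at 1365 CPM in muscle-like nuclei. Of their 3478 UMIs elsewhere, cluster 3 held 1537 (2263 CPM) and cluster 2 held 691 (3800 CPM). Without cluster 3 the fold was 0.748. The low fold is therefore partly a matter of these clusters in the reference.

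Midgut-like nuclei carried more oxidative phosphorylation transcripts and fewer of Notch signalling. Oxidative phosphorylation genes were 2.0-fold higher (1.91 to 2.11), 29 of 65 by at least 2-fold, led by the complex I genes ND-18 (3.36-fold) and ND-23 (3.15-fold). Notch pathway genes were at 0.378 times the level elsewhere (0.272 to 0.512) and ion channels at 0.205 (0.127 to 0.313). With the deepest nucleus of each class left out the oxidative phosphorylation fold was 1.29.

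Salivary gland-like nuclei were dominated by a few transcripts of their own. CG13159 stood at 155555 CPM against 524 CPM elsewhere and CG31813 at 95436 against 634 CPM. In this class 1 nucleus of 36196 UMIs held 73.2% of the UMIs, and without it CG13159 stood at 38595 CPM and CG31813 at 49396 CPM. Axon guidance genes were at 0.435 times the level elsewhere (0.369 to 0.509), with the semaphorin Sema1a on 1 UMI in the class and 954 elsewhere. With the deepest nucleus of each class left out they were at 0.574. Their median log2 fold was -1.32, where matched random lists already had -0.71 in this class. CG13159 also gave the level of RNA outside its own class, since 207 of the 311 other nuclei held a UMI of it, with a median of 1. Likewise Mhc, a gene of muscle, had UMIs in 24 of 57 neuron-like nuclei (median depth 1922 UMIs) and in 41 of 41 muscle-like nuclei (median depth 6798 UMIs). At 1000 UMIs per nucleus these shares were 23.8% and 89.7%.

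**Figure D2:**
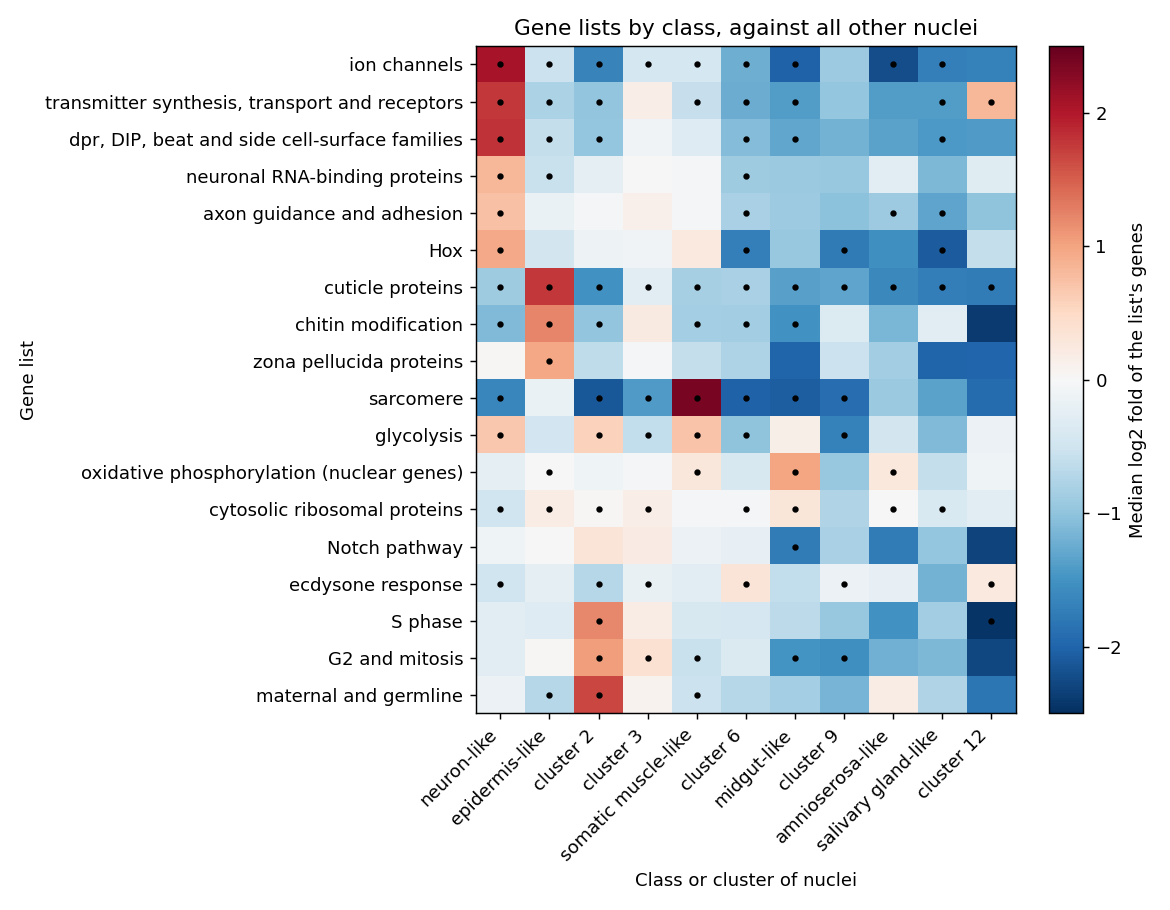
Each cell shows the median log2 fold of the genes of a list (vertical axis) in a class or cluster against all other nuclei (horizontal axis), red where higher and blue where lower. Dots mark medians beyond the 2.5 and 97.5 percentiles of matched random lists, whose own median is not 0, so a pale cell can carry a dot; ion channels in neuron-like nuclei (5.77-fold as a sum) and sarcomere genes in muscle-like nuclei (6.79-fold) stand out.

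Lists of cell division, contraction and transmission differed between unnamed clusters and all other nuclei. In cluster 2, S phase genes were 2.20-fold higher (1.99 to 2.43), all 15 above the other nuclei, led by the replicative helicase subunits Mcm3 (4.02-fold) and Mcm5 (3.32-fold). Genes of G2 and mitosis were 2.26-fold higher there (2.08 to 2.45), with the centromeric histone cid at 7.05-fold (2.86 to 16.5) and the kinase aurA at 3.76-fold. With the deepest nucleus of each class left out the S phase fold was 1.70 and the G2 and mitosis fold 1.97. After thinning they were 1.85 and 2.64. In cluster 3 the genes of G2 and mitosis were 1.35-fold higher (1.26 to 1.44), 15 of 19 members above, with the kinesin pav at 1.88-fold. Sarcomere genes were at 0.283 times the level elsewhere in cluster 3 (0.261 to 0.307), or 0.465 in nuclei thinned to 1000 UMIs. That reference includes the muscle-like nuclei, which held 3936 UMIs of these genes against 2061 in all others. Cluster 3 stood at 973 CPM, and all nuclei outside the muscle-like class, cluster 3 included, at 1182 CPM. The low fold is therefore mostly a matter of muscle in the reference. In cluster 6, transmitter genes were at 0.271 (0.219 to 0.331), or 0.109 when each nucleus was weighed the same. They stood at 512 CPM there, and at 1296 CPM in all nuclei outside the neuron-like class.

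The 8 Hox genes, which set identity along the head to tail axis, were compared in single nuclei to ask which domains were sampled. Genes of the thorax and abdomen prevailed, with 644 UMIs of Ubx, 573 of Antp, 429 of Abd-B and 417 of abd-A. The genes with more anterior domains were scarce, at 78 UMIs of Scr, 40 of Dfd, 24 of lab and 17 of pb. A UMI of any Hox gene was found in 237 nuclei (74.5%, 69.4% to 79.2%) and UMIs of 2 or more Hox genes in 159 (50%). Neuron-like nuclei carried 2.74-fold more Hox RNA than the rest (2.46 to 3.04), with Antp at 3.70-fold and Ubx at 3.26-fold, whereas Scr was at 0.894-fold (0.318 to 2.04). As summed over all nuclei, Hox RNA was lowest in salivary gland-like nuclei (0.204-fold, 0.0974 to 0.375, from 10 UMIs and 0 after thinning) and in cluster 6 (0.274-fold, 0.205 to 0.359, and 0.155 after thinning). With the deepest nucleus of each class left out cluster 9 (0.252-fold) lay below cluster 6 (0.274-fold). Matched random lists had a median log2 fold of -0.76 in salivary gland-like nuclei, against -2.09 for Hox genes. Antp had UMIs in 29 of 57 neuron-like nuclei and in 7 of the 23 deeper nuclei of cluster 6 (median 5521 UMIs).

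An excess of neighbouring Hox genes in the same nucleus was not detectable at this depth in the nuclei as counted. Summed over the 7 neighbouring pairs, both genes were found together 272 times where 241.8 were expected within classes and depth groups, a ratio of 1.12 (0.995 to 1.27). Pairs 2 or 3 apart gave 1.03 (0.919 to 1.15) and pairs 4 or more apart 0.985 (0.814 to 1.18). A nucleus can enter several pairs, so these intervals are too narrow. The lower end for neighbouring pairs passed 1 when 2 or more UMIs were asked for (1.26, 1.06 to 1.49), when only depth was held fixed (1.21, 1.07 to 1.37) and without cluster 3 (1.17, 1.01 to 1.36). Pairs 2 or more apart, at 1.02 in the nuclei as counted, were at 1.15 (0.983 to 1.34), 1.11 (1.01 to 1.22) and 0.988 in the same settings.

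The roX RNAs, long non-coding RNAs that coat the X chromosome of males for dosage compensation, were counted to ask which nuclei carried male dosage compensation. In the table every one of the 318 nuclei held at least 3 UMIs of roX2, so nuclei with and without roX RNA could not be compared. Whether these counts reflect a choice of nuclei or a constant in the table was not settled. The roX2 count was exactly 3 in 174 nuclei, 4 in 67 and 5 in 23, with 54 nuclei at 6 or more and 1516 UMIs in all. No other gene of the table was found in all nuclei. Among 99 genes with a number of UMIs near that of roX2, the widest was found in 257 nuclei and the median in 223. The mean count was 3.44 in the shallowest 106 nuclei, 4.23 in the middle 106 and 6.63 in the deepest 106. For roX1 it was 7.76, 14.1 and 44.7. roX1 was found in 316 nuclei with 7050 UMIs. Sxl, the master gene of female development that also has transcripts in males, had 1500 UMIs in 233 nuclei. msl-2, whose protein assembles the compensation complex, had 69 in 46. The share of UMIs from X-linked genes was not computed, because the reference used here is of another genome release than the one named for the files. All shares of nuclei given here hold for nuclei with 3 or more roX2 UMIs.

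**Figure D3:**
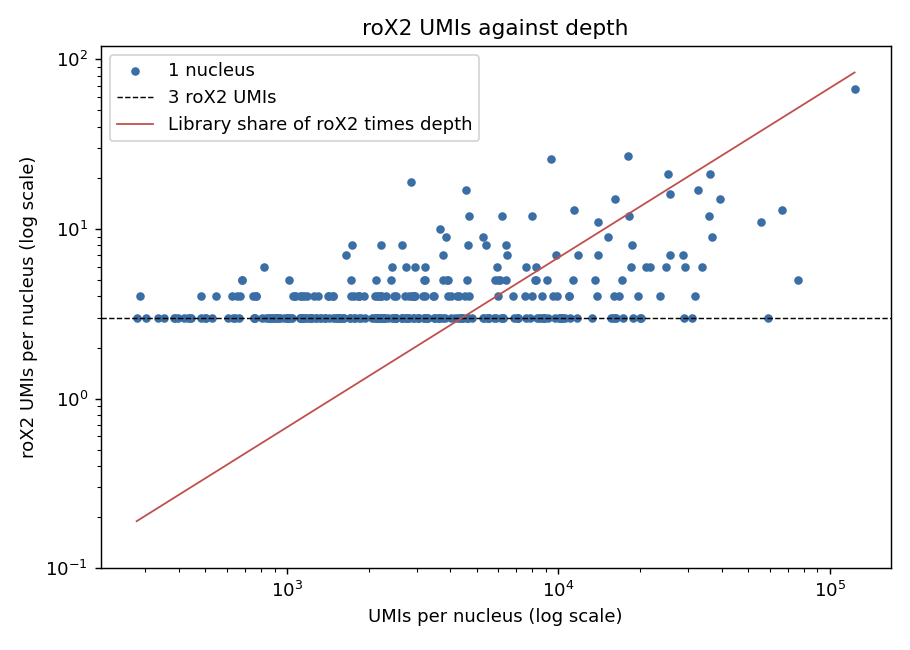
Each point is 1 nucleus, placed by its UMIs (horizontal axis, log scale) and its roX2 UMIs (vertical axis, log scale). No point lies under the dashed line at 3 UMIs, where 174 nuclei sit, and shallow nuclei lie above the red line, the library's share of roX2 times depth.

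Genes with a role in early embryos and genes of late embryos both had UMIs in the library. Maternal and germline genes made up 1767 CPM, and gap and terminal genes, which divide the early embryo into broad regions, 501 CPM. Pair-rule genes made up 645 CPM and cuticle proteins of late embryos, with the reductase Cpr included, 5793 CPM. These sums do not show that early embryos were sampled. The gap genes Kr and hkb were higher in neuron-like nuclei (189 against 78.8 CPM and 52.5 against 8.32 CPM). CycB, also in the list of G2 and mitosis, had 901 of the 3947 maternal and germline UMIs. Maternal genes were 3.52-fold higher in cluster 2 (3.15 to 3.93), with exu, an RNA localization factor of the oocyte, at 14.1-fold and gnu, a regulator of the first divisions, at 7.25-fold. A single nucleus of 59253 UMIs and 6555 genes carried 267 of the cluster's 424 maternal UMIs (63.0%), 466 of its 606 UMIs of dhd and 58 of its 87 UMIs of osk. Maternal genes stood at 4506 CPM in that nucleus (3982 to 5080), and the next highest of the 58 other nuclei with 10000 or more UMIs had 3319 CPM. Without it the fold of cluster 2 was 1.93 (1.63 to 2.28), on 3.57 maternal UMIs per nucleus against 4.98 in the deeper nuclei elsewhere, and the median nucleus of the cluster held 1. When each nucleus was weighed the same the fold was 1.71.

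Patterning genes of the early embryo gave no settled direction in cluster 2. Gap and terminal genes were 1.62-fold higher there (1.27 to 2.03), with the maternal RNAs bcd at 2.49-fold and cad at 2.35-fold, and 2.69-fold higher after thinning. The list's median lay at the 88.7 percentile of random lists, and it turned below 0 without the deepest nuclei. Pair-rule genes were at 0.756 times the level elsewhere (0.600 to 0.941), with the hairy gene h at 0.329 (0.163 to 0.596). The pair-rule fold turned to 1.13 when each nucleus was weighed the same and to 1.15 after thinning.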

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

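The setting with scaled genes and those leaving out the deepest cluster or the deepest nucleus of each class were chosen after seeing the data. No paired analysis was possible because there is 1 library and no second group. The X-linked share and its alternative were not run, for want of chromosomes of the same release, and the setting with every barcode changed nothing, since all nuclei passed. Of 89 values of main results under other settings 55 stayed within their counting interval, or within 1.5 times for counts of pairs, and 34 moved, none with a change of direction. Of 223 further values 188 kept, 31 moved and 4 changed sign. For the values below the cause was not tested unless stated.

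The ribosomal protein share was 22.9% as a mean over nuclei and 25.12% with ribosomal RNA out of the denominator. Shares of 0% mean that no cluster took the name. At resolution 0.5 the epidermis, midgut and amnioserosa shares were 0%. At resolution 2.0 the epidermis share was 11.6%. With 1000 variable genes, at least 500 genes per nucleus, the highest Scrublet scores left out or random seed 1 the midgut and amnioserosa shares were 0%, and without the highest Scrublet scores the muscle share was 9.03%. With 4000 variable genes neurons made up 13.2% and epidermis 11.9%. With Pearson residuals neurons made up 13.8%, epidermis 12.6%, muscle 6.92% and amnioserosa 0%. With comparison lists kept in the clustering epidermis made up 11.6%, midgut 10.7% and amnioserosa 0%. With genes scaled the amnioserosa share was 0%. After thinning to 1000 UMIs, which leaves out 48 shallow nuclei, neurons made up 7.41%, epidermis 11.9%, and midgut and amnioserosa 0%. The adjusted Rand index with the clusters used ran from 0.280 with Pearson residuals to 0.739 with random seed 1.

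Among the list comparisons, 8 of the 109 pairs beyond the percentiles had a median of the other sign when each nucleus was weighed the same, 11 after thinning, 7 without the deepest nucleus of each class, 3 without the deepest cluster, 3 without the member with the most UMIs and 0 with ribosomal RNA out of the denominator. Among the pairs described, the median log2 fold of gap and terminal genes in cluster 2 was -0.11 without the deepest nuclei. That of ecdysone response genes in cluster 9, -0.14 as reported, was 0.18 when each nucleus was weighed the same, 0.022 after thinning and 0.17 without the deepest nuclei. Hox pairs 2 or more apart gave a ratio of 1.15 when 2 or more UMIs were asked for. After thinning 96.7% of 270 nuclei held a roX1 or roX2 UMI, which follows from drawing fewer UMIs. The maternal fold of cluster 2 was 1.71 when each nucleus was weighed the same, 4.08 without the deepest cluster and 1.83 without the deepest nuclei, where the loss of 1 nucleus with 63.0% of the maternal UMIs is the cause.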

Other observations

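The test of depth and that of marker lists for cluster 3, and those of early embryos and of free RNA for cluster 2, were set before their result was seen. The tests of a further cell type and of pooled nuclei for cluster 3, of germ cells for cluster 2 and all those on roX2 were chosen only after the result was seen. No biological explanation from the design was tested, since the study has a single group.

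Cluster 9 (13 nuclei, 4.09%, 2.19% to 6.89%) was higher in markers of several cell types. The lipoprotein gene apolpp stood at 46621 CPM against 3824 CPM elsewhere, and the trehalose synthase gene Tps1 at 653 against 95.4 CPM. The visceral muscle marker Fas3 stood at 6903 against 922 CPM, in all 13 nuclei, and the hemocyte marker glec at 3657 against 392 CPM, in 12. The cluster was led by the cytochrome P450 gene Cyp304a1 (4981 against 47.2 CPM, in all 13 nuclei). Its 10 leading genes also held Cyp18a1, an enzyme that inactivates ecdysone (3283 against 87.2 CPM). No list of steroid metabolism was compared. Markers of the ring gland, which makes ecdysone, were also higher. The marker mld stood at 392 against 77.5 CPM, on 21 UMIs in 8 nuclei, while phm had 6 UMIs and spok 5. Among markers with at least 10 UMIs in the library, 5 of the ring gland had a median log2 fold of 2.20 (3 over 2-fold). For 9 of fat body it was 0.63 (4 over 2-fold), both on the scale with CPM + 10. Fat body and ring gland markers were equally many (4 each), so it was not named. Ecdysone response genes were 2.54-fold higher as a sum (2.30 to 2.79), carried by the nuclear receptor ftz-f1 (8.63-fold, 7.48 to 9.91) and the ecdysone receptor EcR (3.15-fold), and 1.39-fold higher without ftz-f1. Of the 18 members 8 were higher, and the median log2 fold was -0.14 against -0.77 for random lists. Hox RNA was at 0.357 times the level elsewhere (0.215 to 0.560), or 0.235 when each nucleus was weighed the same.

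Cluster 12 (6 nuclei, 1.89%, median 1128.5 UMIs) was higher in the collagen IV genes Col4a1 (5447 against 846 CPM) and vkg (2867 against 458 CPM), both made by hemocytes and fat body, and in the clotting protein fon (2867 against 164 CPM), each on 20 to 38 UMIs. Of 9 fat body markers 8 were over 2-fold higher (median log2 fold 1.89), but only apolpp on 5 or more UMIs, and of 14 hemocyte markers 3 were, 2 of them on 5 or more UMIs. With fewer than 3 markers on that many UMIs for either type, it was not named.

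Every nucleus held at least 3 roX2 UMIs, where Poisson counts at each nucleus's depth would leave 176.1 nuclei under 3, although roX2 RNA is made by males and the labels name no selection by sex. The mean of 3.44 in the shallowest 106 nuclei (3.10 to 3.82) lies far below the 9.84 at which no more than 1 nucleus would fall under 3, which argues against a level of roX2 high enough in every nucleus. Nuclei chosen on a minimum roX2 count remain a candidate explanation. In those shallow nuclei 67.9% sat at exactly 3 and none below, but a constant would give this too, so the share cannot decide between them. A constant added to every nucleus, in the making of the table for instance, is another: of the 562 UMIs beyond 3 per nucleus 8.36% lay in the shallowest 106 nuclei, within the 2.44% to 9.27% of 397 genes with about as many UMIs. Nuclei kept from 3 on, with roX2 at 1 rate in all of them, would have 2.27% there, which goes against a choice in that simple form. Rates that differ between nuclei were not tried. With a constant a count of 3 would say nothing about the sex of a nucleus. None of these tests used roX1, whose counts a constant on roX2 would not change. It was found in 316 nuclei on 7050 UMIs, against 301 for RpL13 on 7057 UMIs and 303 for RpL24 on 7028.

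Cluster 3 was the deepest and had few genes of its own. With all nuclei thinned to 1000 UMIs, the largest group of its 45 nuclei that stayed together was 31.1%, the lowest among the clusters, against 47.6% to 100% in the others, so depth alone may have brought them together. The neuron-like cluster, at 47.6%, also fell under the 50% set for that test, which therefore separates weakly. Several nuclei or free RNA under 1 barcode stay open: at 1000 UMIs a median of 4 of the 6 class marker lists had a UMI (95% interval of the median 4 to 5), at or under the highest of the named classes as the bar against this explanation asked, but that class has 8 nuclei and a median of 6 (3 to 6), so the difference lies within the spread, and pools of 2 nuclei of different classes gave a median of 5. A further cell type stays open as well, because its 4 genes led by 5-fold or more, on the scale with CPM + 10, are the pattern itself, against 11 or more in the clusters of named classes with 15 or more nuclei.

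Cluster 2 was led by maternal transcripts, at 1.93 times the level elsewhere (1.63 to 2.28) without the single nucleus that supplied 63.0% of its maternal UMIs. None of the explanations tested was excluded. Nuclei of early embryos could be a source, but the 22 gap and pair-rule genes, at 0.941 times the level elsewhere (0.809 to 1.09), met neither the 2-fold set for this explanation nor a value under 1. Free maternal RNA shared by all nuclei could not be told apart either: across 21 maternal genes, which are not independent, UMIs in the cluster and in the named classes had a Spearman rho of 0.789, just under the bar of 0.8, and 0.817 with cluster 6 counted among the classes. Germ cells stay open too, since at 1000 UMIs 25.7% of its nuclei held a germ cell gene (12.5% to 43.3%) against 10.6% of the others (7.0% to 15.3%), which met neither the 50% nor the 25% set for this test.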
